A study of Homo sapiens with 6 samples.

How the data were processed

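Total RNA of RKO cells was extracted with TRIzol and made into libraries with a commercial RNA-seq kit, per the labels' protocols. The samples were 3 libraries labelled shNC and 3 labelled shKMT5A. Each column of values was assigned to a sample by the treatment and the number in its name. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the build GRCh38 (hg38). Whether counting used the strand is not given in the sources used here, so values of overlapping antisense genes are uncertain, as are those of near-identical gene copies (HLA, histone, keratin, protocadherin and zinc finger genes, EIF3CL, SMIM11).

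The deposited signal values are gene read counts that the authors divided by 1 factor per library, as shown by the values: in each column 100% of values were whole multiples of the value of 1 read (within 0.001 of a whole number). The value of 1 read ranged from 0.9522 to 1.047. Whole reads were taken as recovered for 5 libraries, and tests on reads used those 5. In shKMT5A replicate 3 the value of 1 read, 0.9935, was too near 1 for the check of the unit used here. Its values were still whole multiples as closely as in the other columns (largest distance from a whole number 4.8e-06). Leaving it out of these tests was therefore a choice and not forced by the values. The deposited log2 fold changes, p-values and adjusted p-values are the authors' own, and the file's group means matched the means of the columns. The authors' table keeps only genes that passed an absolute log2 fold change of 1 and an adjusted p of 0.05, judged from its values. It holds 2036 protein-coding genes and 849 of other classes. Scaling, library totals and gene set backgrounds can therefore not be checked against all genes, tests within the table run on preselected genes, and nearly all pass by construction. Spreadsheet software had turned 5 gene names into dates, which were resolved by identifier. Of 2885 identifiers, 2872 had a current symbol in a table of gene names, and 549 symbols differed from those in the file. Positions are those of the file and were checked against GENCODE 29 (GRCh38): 2884 were identical to those of the row's identifier. The exception is the row named IFNB1, which carries the position and length of IFI27; it was kept under its identifier, and the counts of genes, the named genes and the lists were also computed without it.

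The design had been written before the data were examined, with edgeR for raw counts and limma for normalized values, and the values called for the latter. Genes with a mean of at least 1 normalized count were tested with limma 3.58.1 (trend, robust; statmod 1.5.0, R 4.3.3) on log2(value + 1), shKMT5A minus shNC, with Benjamini-Hochberg adjustment over the table and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. Where all libraries of a group were at 0, a bound was computed against a floor of 3 counts over the group, which covers counting error only. Intervals of ratios resting on 1 to 3 reads are exact Poisson intervals at 95%, also for counting error only. KMT5A was also tested by an exact permutation test (scipy 1.17.1, Python 3.11.15). The 22 gene lists (748 distinct genes, 205 in the table) had been fixed in advance. The 19 lists with at least 2 genes in the table were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with the rest of the table. With the preset correlation 10 lists passed, and with an estimated correlation 0 passed, the lowest adjusted p being 0.293; before adjustment 2 lists (cytokines, G1/S) had p under 0.05. By fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, all 19 passed. Single genes were named by a rule fixed in advance: 15 genes of the pathway where measured, the 6 highest and 6 lowest fold changes without overlap between groups, and the 2 strongest members of each list other than markers, ribosomal and mitochondrial genes. Further members are given as examples of their list. Some genes that the rule names are not reported here.

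Data were simulated with 200 of the 2883 genes tested changed and a dispersion (variance beyond counting noise) of 0.02 for every gene. There limma recovered 75% of genes changed 2-fold and 96% of those changed 4-fold, with 10 false calls among 2683 unchanged genes. Nearly all genes of the real table differ, so these rates do not carry over to it. In the simulated data camera called 10 of 200 randomly drawn sets at p under 0.05 with the preset correlation and 2 with the estimated one, and fry called 51. These sets could include some of the 200 changed genes, so not all calls by fry need be false. The genes were simulated independently of each other. The rates therefore do not carry over to real lists whose genes vary together, such as the interferon-stimulated list (estimated correlation 0.457). In the real data the other splits of the libraries into 3 and 3 called 5 to 9 lists with the preset correlation, against 10 for the real split. Part of the real difference remains in those splits, so these counts are not a rate of false calls. Alternatives were another pseudocount (0.1), no filter, equal library medians, the replicate number as a block, a fold threshold and each library left out. Chosen after seeing the data were edgeR 4.0.16 with 3 scalings and DESeq2 1.42.0, all on the recovered reads of 5 libraries, and the fit without the row named IFNB1. On these reads edgeR with the authors' factors called 1653 genes higher and 1228 lower.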

Results

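RNA sequencing was carried out on RKO, an established human colorectal carcinoma cell line. The 6 libraries formed 2 groups of 3. The control group was labelled with a non-targeting short hairpin RNA (shNC), and the other group was labelled with a hairpin against KMT5A (shKMT5A). KMT5A, also called SETD8, is the methyltransferase that places a single methyl group on lysine 20 of histone H4. The series title names methylation of the transcription factor IRF3 by KMT5A and immune suppression, so the comparison of the groups addresses which genes, and among them which immune genes, differed with the hairpin. The labels do not say whether the shKMT5A libraries carried different hairpins or came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

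The deposited table held 2885 genes, each with a normalized read count in the 6 libraries. Every gene in it had an adjusted p of at most 0.0499 and an absolute log2 fold change of at least 1 in the authors' deposited table. The values therefore describe genes the authors had already selected as different, and genes outside the table were not analysed here. Reads assigned to these genes ranged from 1363382 to 1369655 in the shNC libraries and were 1891460 and 1906015 in shKMT5A replicates 1 and 2, and the total depth of the libraries is unknown. Differences between replicates had 2.36 to 9.60 times the variance of counting noise.

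KMT5A, the targeted gene, was higher in the libraries labelled shKMT5A, which goes against that label. KMT5A (ENSG00000183955, chromosome 12, 123383773 to 123409358, plus strand, GRCh38) had 1298, 1245 and 1307 normalized counts in the shNC libraries and 4015, 3898 and 3297 in those labelled shKMT5A. The means were 1283 ± 33.8 and 3737 ± 386 (SD, n = 3 each), a 2.91-fold difference with no overlap between the groups. The log2 fold change was 1.54 with a standard error of 0.075 (limma, adjusted p = 1.00e-08). An exact two-sided permutation test of the normalized counts gave p = 0.1, the smallest that 3 against 3 libraries allow. The authors' deposited table lists the same direction, with a log2 fold change of 1.54. All directions below are those of the libraries labelled shKMT5A against those labelled shNC, and none can be read as the effect of less KMT5A transcript.

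**Figure D1:**
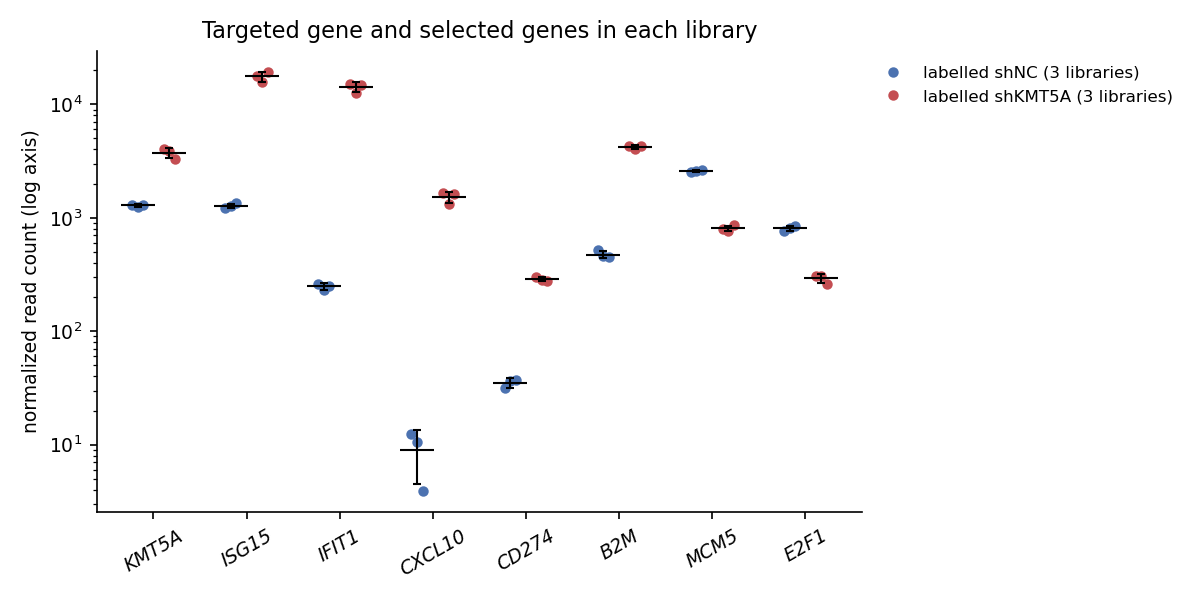
Normalized read counts (log axis) of KMT5A and 7 other genes in each library, with points for single libraries and black bars for the mean and SD of 3 libraries. KMT5A lies near 1283 in the libraries labelled shNC and near 3737 in those labelled shKMT5A, and no gene shown overlaps between the groups.

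Genes higher in the libraries labelled shKMT5A outnumbered lower ones with the authors' scaling. Of 2885 genes tested with limma, 1655 were higher, 1228 were lower and 2 did not pass an adjusted p of 0.05. The 2 were EIF3CL and SMIM11, named after their values were seen, with adjusted p of 0.0515 and 0.204. Without shNC replicate 2, EIF3CL passed as lower (adjusted p = 3.40e-06), and the log2 fold change of SMIM11 was 0.95 with all libraries, -0.05 without shKMT5A replicate 2 and 1.56 without shKMT5A replicate 3. With an absolute log2 fold change of at least 1 as well, 1630 were higher and 1218 lower; with edgeR on the reads of 5 libraries that balance turned to 938 and 1228 (TMM) and to 974 and 1228 (totals over the table). The groups did not overlap for 2876 genes (99.7%, against 10% by chance for 3 against 3), which follows in part from the authors' selection. On the log2(value + 1) scale the highest fold changes were those of HEPH, a ferroxidase, IFI44L, MX2 and OAS2, which are interferon-stimulated genes, COL8A1, a collagen chain, and a row named IFNB1 that is described with the cytokines. With a pseudocount of 0.1, which raises genes at 0 in the shNC libraries, only HEPH and COL8A1 stayed among the 6 highest. HEPH and COL8A1 had no read in any shNC library and 357 ± 18.8 and 267 ± 10.4 normalized counts in those labelled shKMT5A, at least 369-fold and 276-fold higher against a floor of 3 counts over the group. MX2 went from 35.7 ± 8.36 to 11370 ± 1456, and OAS2, which makes the second messenger of RNase L, from 47.9 ± 5.85 to 12651 ± 1356.

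On the same scale the lowest fold changes were those of the zinc finger genes ZNF875 (HKR1 in the table), ZNF793, ZNF738 and ZNF331, all on chromosome 19, of the collagen gene COL6A6 and of the non-coding LINC01036. ZNF875 had 651 ± 59.6 normalized counts in the shNC libraries and 0 in all 3 libraries labelled shKMT5A, at least 638-fold lower. ZNF793 had 448 ± 3.23 and 0, at least 439-fold lower. ZNF738, LINC01036 and ZNF331 were likewise at 0 in the libraries labelled shKMT5A and had 229 ± 23.3, 209 ± 18.7 and 190 ± 16.1 in the shNC libraries. COL6A6 fell from 683 ± 49.6 to 1.38 ± 1.2, a 495-fold difference that rests on very low counts in the libraries labelled shKMT5A. With a pseudocount of 0.1, all but COL6A6 stayed among the 6 lowest. Adjusted p for these 6 genes lay between 7.09e-11 and 7.13e-09.

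**Figure D2:**
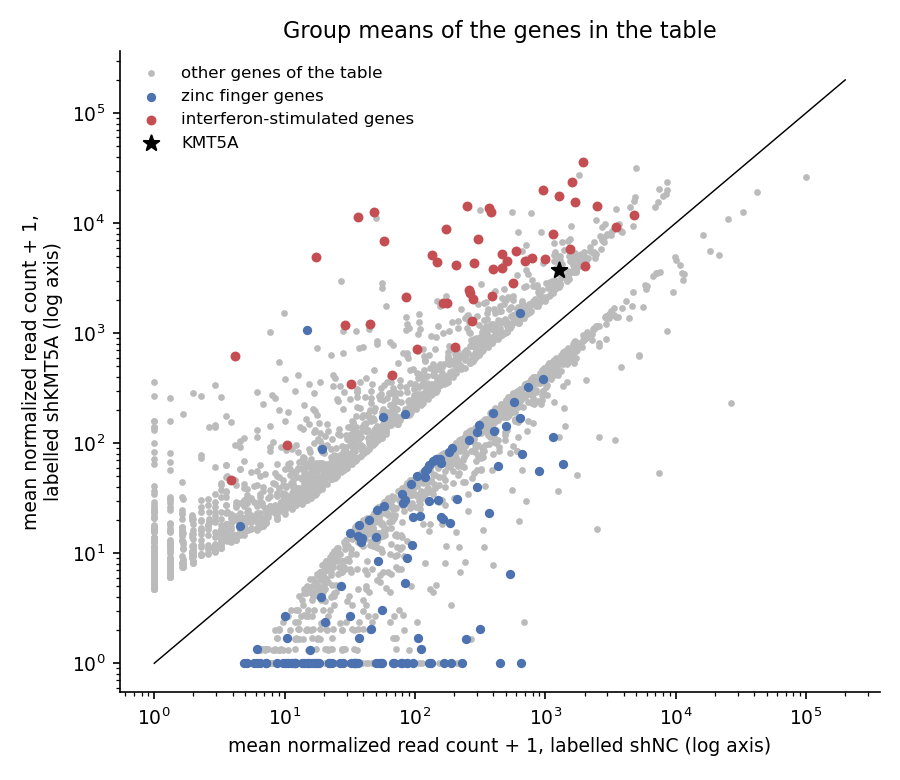
Mean normalized read count plus 1 (log axes) of each gene in the libraries labelled shNC (x) and shKMT5A (y), with 1 point per gene of the table and the line of equal means. Interferon-stimulated genes (red, 50 genes) lie above the line, most zinc finger genes (blue, 123 of 129) lie below it, and KMT5A (star) lies above it; the empty band along the line reflects the authors' selection.

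**Figure D3:**
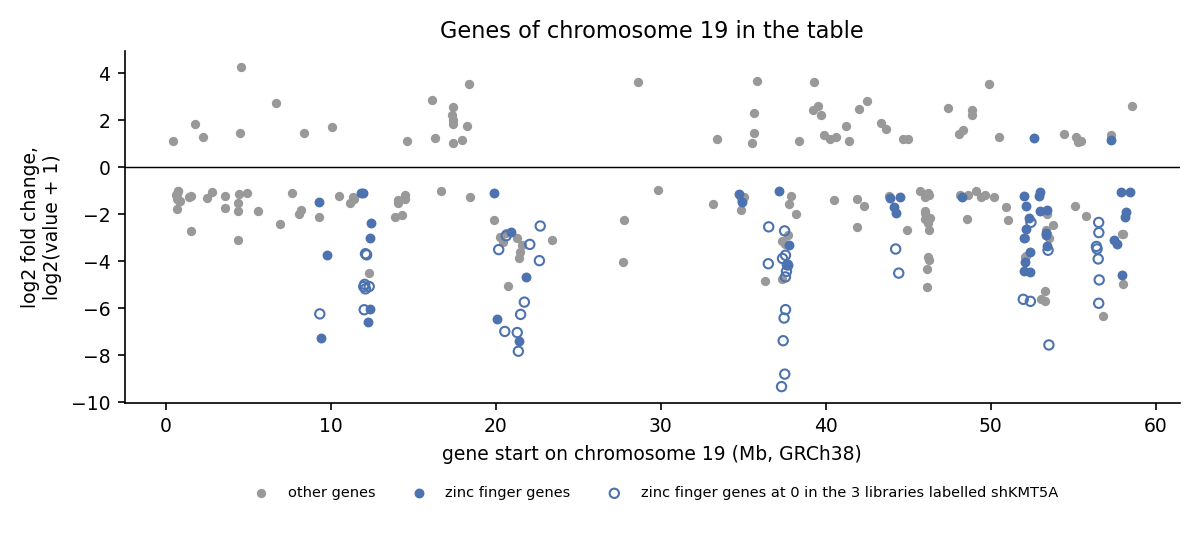
Log2 fold change on the log2(value + 1) scale (y) of the 258 genes of chromosome 19 in the table against their start in Mb on GRCh38 (x), with zinc finger genes in blue and, as open circles, those with no read in the 3 libraries labelled shKMT5A. Of the 258 genes 202 lie below 0, among them ZNF875, ZNF793, ZNF738 and ZNF331.

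Interferon-stimulated genes rose together in the libraries labelled shKMT5A, in which KMT5A was also higher. Of the 55 genes of the list, 50 were in the table, and all 50 were higher (50 also when adjusted over the list alone). Passing over the list alone follows largely from the authors' selection, for this list and those below. Their median log2 fold change was 3.41, and the ratios of means ran from 2.02 to 318. ISG15, a ubiquitin-like modifier, had 1272 ± 62.8 normalized counts in the shNC libraries and 17628 ± 1762 in those labelled shKMT5A (n = 3 each). IFIT1, which binds viral RNA ends, had 248 ± 16.6 and 14182 ± 1392, a log2 fold change of 5.83 ± 0.081 (SE). IFI44L went from 16.4 ± 10.5 to 4943 ± 287. Against the rest of the table the list was higher with a preset correlation (camera, adjusted p = 1.01e-12), and adjusted p = 0.309 with an estimated correlation.

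Sensors of nucleic acids and factors upstream of IRF3 moved in the same direction. All 10 of the 28 list genes in the table were higher in the libraries labelled shKMT5A (10 adjusted over the list alone), with a median log2 fold change of 3.20, and 4 of them are also in the interferon-stimulated list. RIGI, the cytosolic RNA sensor RIG-I, had 302 ± 24.9 normalized counts in the shNC libraries and 7166 ± 533 in those labelled shKMT5A. IFI16, a DNA sensor, had 86.4 ± 16.6 and 1203 ± 161. The list passed the camera test (adjusted p = 0.00117), with adjusted p = 0.309 with an estimated correlation. IRF3, CGAS, STING1 and TBK1 were not among the genes of the table and were not analysed here.

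Cytokine and chemokine genes and targets of NF-kB were higher as well. All 24 of 40 list genes in the table were higher in the libraries labelled shKMT5A (24 adjusted over the list alone), with a median log2 fold change of 4.28 (camera, adjusted p = 2.12e-05; adjusted p = 0.293 with an estimated correlation). CXCL10, a chemokine that attracts T cells, had 8.97 ± 4.45 normalized counts in the shNC libraries and 1529 ± 170 in those labelled shKMT5A, and CCL5 had 5.17 ± 3.01 and 112 ± 9.29. CXCL8 went from 313 ± 43.1 to 13040 ± 2582, and TNF from 10.9 ± 2.26 to 299 ± 24.8.

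The identity of the row named IFNB1, the gene for interferon beta, is uncertain. Its identifier (ENSG00000171855), name and description are those of IFNB1, but its position (chromosome 14, 94104836 to 94116698, plus strand) and its length of 4147 bases are those of IFI27, an interferon-stimulated gene, in GENCODE 29. In that annotation IFNB1 lies on chromosome 9 at 21077105 to 21077963 on the minus strand and is 859 bases long. The other 2884 rows carried the position and length of their own identifier, and no other row carried the identifier of IFI27. The row had 49.3 ± 6.74 normalized counts in the shNC libraries and 11043 ± 2001 in those labelled shKMT5A (n = 3 each), a log2 fold change of 7.77 ± 0.136 (SE), which is not reported here as the expression of IFNB1. Without the row, a choice made after seeing the data, 23 of 23 cytokine genes were higher with a median log2 fold change of 4.22 (camera, adjusted p = 4.18e-05; adjusted p = 0.2925 with an estimated correlation), and FYB1, an adaptor protein gene, took its place among the 6 highest with 1 read in the shNC libraries and 257 ± 31.4 normalized counts in those labelled shKMT5A.

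Genes of antigen presentation by MHC class I rose by smaller factors. All 13 of 22 list genes in the table were higher in the libraries labelled shKMT5A (13 adjusted over the list alone), with a median log2 fold change of 1.62 (camera, adjusted p = 5.53e-04; adjusted p = 0.293 with an estimated correlation). B2M, the light chain of MHC class I, went from 474 ± 36.5 to 4194 ± 160, and NLRC5, the transactivator of these genes, from 318 ± 15.8 to 2793 ± 259. Ligands and enzymes of immune checkpoints were higher for all 6 of 25 list genes in the table (6 adjusted over the list alone; median log2 fold change 3.54; camera, adjusted p = 0.0230; adjusted p = 0.293 with an estimated correlation). CD274, which encodes PD-L1, went from 35.1 ± 3.22 to 288 ± 11.8. IDO1, a tryptophan-degrading enzyme, went from 5.16 ± 4.93 to 288 ± 57.9, and LGALS9 from 7.06 ± 1.91 to 272 ± 24.0. The log2 fold change of IDO1, 5.89 with all libraries, was 5.24 without shNC replicate 1 and 6.52 without shNC replicate 2, where its shNC mean was 2.44.

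**Figure D4:**
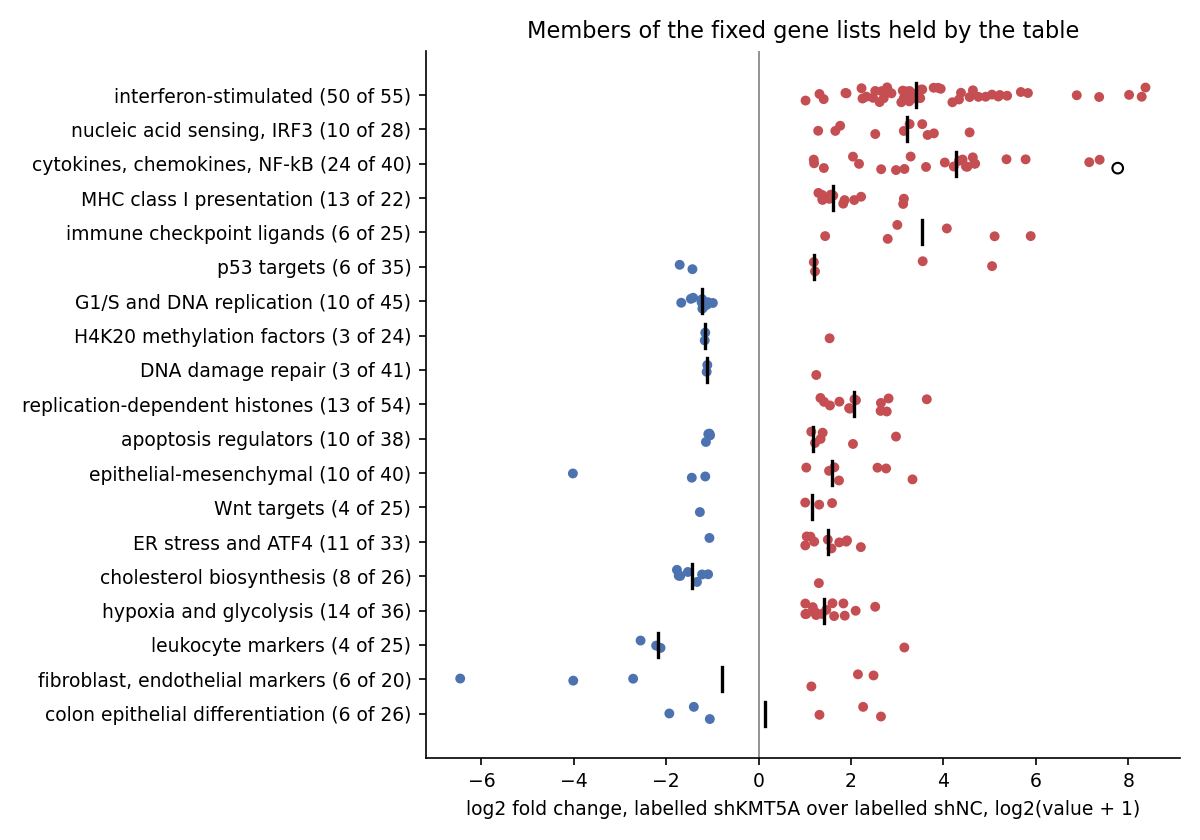
Log2 fold change on the log2(value + 1) scale (x) of each gene of 19 fixed lists held by the table (rows, with the number in the table of the number fixed), red for higher and blue for lower in the libraries labelled shKMT5A, with a black bar at the median of each list. The interferon-stimulated list has its median at 3.41 and the G1/S list at -1.22; the open circle is the row named IFNB1 whose position is that of IFI27.

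DNA replication genes fell while replication-dependent histone genes rose in the libraries labelled shKMT5A. All 10 of 45 genes of the G1/S and DNA replication list in the table were lower (10 adjusted over the list alone), with a median log2 fold change of -1.22 (camera, adjusted p = 5.53e-04; adjusted p = 0.293 with an estimated correlation). MCM5, a subunit of the replicative helicase, went from 2582 ± 64.7 to 809 ± 44.1 normalized counts, and E2F1, a transcription factor of S-phase entry, from 807 ± 39.0 to 292 ± 25.9. Of 54 histone genes 13 were in the table, and all 13 were higher (13 adjusted over the list alone), with a median log2 fold change of 2.07 (camera, adjusted p = 0.0230; adjusted p = 0.293 with an estimated correlation). With DESeq2 on the reads of 5 libraries the histone list no longer passed (adjusted p = 0.3805). H2BC8 had no read in the shNC libraries and 6.42 ± 3.10 normalized counts in those labelled shKMT5A, at least 6.65-fold higher. H3C6 had 3 reads over the shNC libraries, and its ratio of 22.4 had a 95% counting interval of 7.60 to 108 and was 45.1 without shNC replicate 2. None of the 45 genes of the G2/M list was in the table, and MKI67 and CDKN1A were not analysed here. Of 24 factors of H4K20 methylation 3 were in the table: KMT5A, which was higher, and SKP2 and TONSL, which were lower (camera, adjusted p = 0.449). TONSL went from 2000 ± 135 to 892 ± 72.4.

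Targets of p53 moved both ways. Of the 35 list genes 6 were in the table (6 adjusted over the list alone). GDF15, EDA2R, GADD45A and PMAIP1 were higher and PLK2 and CYFIP2 were lower, 4 and 2 of the 6 (camera, adjusted p = 0.668). GDF15, a stress-induced cytokine, went from 67.3 ± 14.2 to 787 ± 12.1 normalized counts. EDA2R had no read in the shNC libraries and 33.5 ± 10.96 in those labelled shKMT5A, at least 34.7-fold higher. Of 41 DNA repair genes 3 were in the table, with XRCC4 higher and TIMELESS and CHEK2 lower (camera, adjusted p = 0.423). XRCC4 went from 55.1 ± 4.89 to 132 ± 13.5 and TIMELESS from 2457 ± 47.3 to 1127 ± 12.3.

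Stress and oxygen-response genes held by the table mostly rose, and its sterol synthesis genes mostly fell, in the libraries labelled shKMT5A. Of 33 genes of the ER stress and ATF4 list 11 were in the table, where 10 were higher and CRELD2 was lower (11 adjusted over the list alone). Their median log2 fold change was 1.5 (camera, adjusted p = 0.0134, and 0.314 with an estimated correlation). PPP1R15A, which directs removal of phosphate from eIF2 alpha, went from 1489 ± 44.5 to 6906 ± 133, and NUPR1 from 359 ± 42.6 to 1348 ± 68.5. All 14 of 36 hypoxia and glycolysis list genes in the table were higher (14 adjusted over the list alone). Their median log2 fold change was 1.41 (camera, adjusted p = 0.00188, and 0.577 with an estimated correlation). CA9, carbonic anhydrase 9, went from 35.1 ± 3.01 to 211 ± 51.7, and NDRG1 from 1165 ± 27.3 to 5125 ± 1424. Of 26 cholesterol synthesis genes 8 were in the table, where 7 were lower and STARD4, a sterol carrier, was higher (8 adjusted over the list alone). Their median log2 fold change was -1.43 (camera, adjusted p = 0.0058, and 0.309 with an estimated correlation). ACAT2, a cytosolic thiolase, went from 2924 ± 118 to 883 ± 65.8.

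The remaining lists did not pass the camera test. Of 38 apoptosis regulators 10 were in the table, 6 higher and 4 lower (camera, adjusted p = 0.635). CASP1, the inflammatory caspase, went from 10.3 ± 3.84 to 86.7 ± 20.5 and BIRC3 from 516 ± 22.8 to 2143 ± 307. The epithelial-mesenchymal list of 40 genes had 10 in the table, 7 higher and 3 lower (camera, adjusted p = 0.449). ZEB1, a repressor of epithelial genes, went from 24.4 ± 4.15 to 253 ± 18.7. ITGB6 went from 63.3 ± 14.98 to 3.43 ± 2.66 (a mean of 2 without shKMT5A replicate 1). Of 25 targets of Wnt signalling 4 were in the table, 3 higher and 1 lower, FGF18 (camera, adjusted p = 0.393). APCDD1 went from 1257 ± 53.4 to 3782 ± 71.8 and EPHB2 from 204 ± 17.1 to 507 ± 20.4. The table held 0 of the 65 genes of the ribosomal protein list and 0 of the 13 genes of the list of mitochondrially encoded proteins.

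Markers of other cell types went both ways. Of 4 leukocyte markers in the table, CD8A was higher (0.64 ± 0.55 and 13.2 ± 3.53 normalized counts) and CORO1A, GZMB and CD79A were lower, with CORO1A, an abundant leukocyte transcript, going from 490 ± 27.3 to 105 ± 12.9 (camera, adjusted p = 0.413). Of 20 fibroblast and endothelial markers 6 were in the table, 3 higher (COL3A1, ACTA2, CDH5) and 3 lower (LUM, DCN, TEK), with adjusted p = 0.584 (camera). Of 26 colon epithelial markers 6 were in the table and also split 3 and 3 (camera, adjusted p = 0.423, and 0.01717 with DESeq2 on the reads of 5 libraries). The keratins KRT8, KRT18 and KRT19 were lower, KRT8 going from 100213 ± 4818 to 26247 ± 395, and MUC2, CDH17 and AGR2 were higher.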

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

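The tests on recovered reads and the fit without the row named IFNB1 were chosen after seeing the data. Directions drawn here are those of the libraries labelled shKMT5A, in which KMT5A was higher. The counts of genes past an adjusted p of 0.05 stayed within 1.5 times of 1655 and 1228 under every alternative run. The authors had selected all these genes as different in the same libraries. Stable counts, directions and sides of the threshold are therefore largely built in. Leaving out 1 library gave 1647 to 1653 higher and 1225 to 1228 lower genes, and the fold threshold gave 1630 and 1218. No gene changed sign under any alternative except SMIM11, without shKMT5A replicate 2. Scaling shifted the median fold change of the table by -0.24 (equal medians), -0.62 (TMM) and -0.56 (table totals), and the higher genes numbered 1652, 1492 and 1525. With the fold threshold as well these scalings gave 1313, 938 and 974 higher genes against 1229, 1228 and 1228 lower, so with TMM and table totals lower genes outnumbered higher ones; since the table holds only selected genes, such scalings are not better founded than the authors'. DESeq2 on the reads of 5 libraries called 1607 and 1207. The log2 fold change of KMT5A ranged from 0.99 to 1.63 over the alternatives and stayed past the threshold. The 46 genes that the naming rule chose kept their direction and their side of the threshold wherever tested. With an estimated correlation, camera gave adjusted p of 0.309 for the interferon-stimulated and the nucleic acid sensing lists. It gave 0.293 for the cytokine, MHC class I and G1/S lists, so none passed. The estimate replaces the preset correlation and is higher than it for these lists. A higher correlation is not the whole reason for the loss. The immune checkpoint list had an estimate of -0.168, below the preset 0.01, yet its unadjusted camera p rose from 0.0121 to 0.0618. With DESeq2 the histone list no longer passed (adjusted p = 0.3805; range over alternatives 0.01724 to 0.3805) and the colon epithelial list passed (0.01717, range to 0.5799); the cause was not tested. Same-numbered libraries of the groups did not deviate together (correlations -0.035, -0.038 and 0.001), so these values show no pairing by number. They cannot exclude a weak one, since genes with few reads are included, and the labels do not say whether the numbers pair samples. With the replicate block 1655 and 1228 genes passed. The filter on low values removed no gene, so that alternative says nothing. The alternatives planned for raw counts (limma-voom, RLE factors, no TMM, DESeq2 with its own factors) were not run as written. Depth is known only for the genes of the table, and genes with few reads carry large intervals.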

Other observations

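The groups described first were chosen after seeing the data, and their Fisher's exact tests (direction against the rest of the table, adjusted over 5 groups) only describe it; KMT5A was higher in the libraries labelled shKMT5A, to which all directions refer. Genes with zinc finger symbols, pseudogenes and antisense transcripts included, were lower for 123 of 129 in the table (adjusted p = 8.96e-39), with a median log2 fold change of -3.09, and 54 of them had no read in any library labelled shKMT5A. Of the 129, 94 lie on chromosome 19, where 202 of 258 genes were lower (78.3%); among the 164 other genes of that chromosome 110 were lower and 54 higher. An exception was ZNF521, which rose from 13.9 ± 8.06 to 1071 ± 64.3 normalized counts. TRIM28, the corepressor bound by many zinc finger proteins, was 6.003-fold higher (1581 ± 97.4 and 9490 ± 546). Clustered protocadherin genes on chromosome 5 were lower for 24 of 24 (adjusted p = 2.80e-09), with low counts, 69.6 ± 16.3 in the shNC libraries for PCDHB2.

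HLA class II genes and CD74, the class II invariant chain, were higher for 9 of 9 in the table (adjusted p = 0.0159), CD74 going from 26.03 ± 4.03 to 2979 ± 204 and HLA-DRA from 89.3 ± 16.5 to 1120 ± 157. Of a set of cytosolic and mitochondrial chaperone genes picked by symbol, 10 of 11 in the table were lower (adjusted p = 0.00217), HSPA8 going from 21697 ± 1505 to 5162 ± 940 and HSP90AA1 from 18218 ± 522 to 5558 ± 232; CCT6B was higher, as were DNAJB9, DNAJC1 and HSPB9, which are outside the set. Keratin genes split into 14 higher and 12 lower (adjusted p = 0.843), with KRT17 going from 26757 ± 1305 to 233 ± 53.4 and KRT7 from 109 ± 15.9 to 1086 ± 71.8. GATA3, a transcription factor, went from 6.77 ± 1.75 to 1027 ± 94.3, and DHRS2 from 1820 ± 70.6 to 27302 ± 1614.

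In the patterns that follow, all tests were chosen after the result was seen, except the percentage of gene clusters that hold an expressed gene. KMT5A was 2.91-fold higher in the libraries labelled as its knockdown. Scaling to totals over the table does not account for it, since the log2 fold change was then still 1.05 with the reads of 5 libraries. These totals cover only selected genes, so another scaling cannot be excluded. The row of the pseudogene KMT5AP1 gained 29.6 normalized counts against 2453 for KMT5A. Pseudogene reads counted as KMT5A would not appear in that row, so its small gain cannot exclude them. An exchange of the group labels stays open, because the ratio of 2.91 is what it would need and no other label identifies the groups; if it held, every direction given here would turn round. A rise of KMT5A transcript in cells that carry the hairpin was not tested.

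Genes at 0 in all 3 libraries of 1 group and at 10 or more normalized counts in every library of the other numbered 81 for the libraries labelled shKMT5A (34 of them zinc finger genes) and 34 for shNC. Counting noise at low depth cannot produce them all, since 17 had 100 or more in every library of the other group. Of the 81, 57 fall into 11 clusters of neighbours, and 3 clusters (27.3%) hold an expressed gene of the table. In 1 of these, on chromosome 19 from 51964343 to 53580269, 14 expressed genes split the 7 genes at 0 into 5 runs, the longest with 42.9% of them, so a single contiguous deletion does not account for most of that cluster. Expressed here means 10 or more normalized counts in every library labelled shKMT5A. Many of the 14 were themselves lower there, such as ZNF432 (1378 ± 99.0 to 64.0 ± 1.75), while ZNF83 was higher (644 ± 22.4 to 1521 ± 56.0). A single deletion stays open for most genes of the other 10 clusters, because unchanged genes inside them are not in the table. In 2 of the 10, a single expressed gene leaves 10 of 11 and 5 of 7 genes at 0 on the same side. Some genes of the table inside the 10 kept reads below the limit of 10 normalized counts. In the libraries labelled shKMT5A, ZNF44 had 5.47 ± 4.27 and PCDHB14 had 3.39 ± 1.12, while others, such as ZNF20 and PCDHB11, were at 0. Values this low in families of near-identical copies cannot decide the question. Different cell populations in the groups, such as separate clones, may also account for the pattern, as at least 7 genes with 100 or more counts were at 0 in each direction, and cannot be told apart from an effect of the hairpin because every library of a group shares both.

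Interferon-stimulated genes were higher for 50 of 50 in the table. Scaling to totals over the table does not account for it: their median log2 fold change was then 2.79 and the lowest 0.42. These totals cover only selected genes, so another scaling cannot be excluded. Leukocytes in the cultures stay open: the leukocyte markers had a median of -2.17, but only 4 of 25 are in the table, they went both ways, and the level of CORO1A in the shNC libraries, 490, would hide a small share. A response to the hairpin vector and not to KMT5A stays open, because the labels give 1 treatment with a KMT5A hairpin, no rescue, and no second hairpin told apart. A difference that follows KMT5A, whose own direction goes against the label, is the biological explanation the design names and was not tested separately.

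The splits of the 6 libraries into 3 and 3 number 10, the real one included, so their share cannot fall under 0.05. The real split gave 1655 higher and 1228 lower genes and 10 gene lists; 1 split, the real one, gave results as large, and the highest of the other splits were 0, 0 and 9. Each of the other 9 splits called 5 to 9 lists at the preset correlation, so the number of lists does not by itself set the real split apart. These splits hold the 2 groups in unequal numbers on their 2 sides, so part of the real difference remains in them. Their list counts are therefore not a rate of false calls. The 0 counts are limma's at an adjusted p of 0.05, and at an unadjusted p under 0.05 the other splits gave at most 6 genes; genes were selected for the table on the real split.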
